A study of Mus musculus with 2 samples.

How the data were processed

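H3K4me3 ChIP-seq was done on 2 biological replicates of mouse forebrain at embryonic day 12.5, each a pool of embryos of both sexes, with 120 embryos in replicate 1 and 68 in replicate 2, per the labels. The labels also give a size range of 300 to 500 for both libraries, with no unit. The 4 deposited peak lists were used: the list of each replicate, called on that replicate alone, a pooled list from both replicates together, and a list of replicated peaks made from the other 3, per the file headers. Each replicate's list was derived from its own alignments and 1 further file, which was a different file for each replicate, per the file headers. The coordinates are on mm10, per the file headers. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here.

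The lists are in narrowPeak format, per the file headers. The deposited fold of a peak, a ratio to background, was read from the signal column, where all values lay above 1. It was used only to describe, rank or filter peaks within a list. The deposited −log10 p-value of every peak was at least 2.00, and the deposited −log10 q-value, used for stricter filters at 2 and 5, went down to 0.163. The authors' lists thus held peaks with weak support: 3.00% of replicate 1 peaks and 2.89% of replicate 2 peaks had a q-value above 0.05, against 0.0426% of replicated peaks. No list gives read counts, so the depth of each library is unknown, and no interval that needs depth is given. A library with more reads yields more short, weak peaks, and a difference in the number of peaks between replicates can come from depth.

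Every replicated peak was identical to a pooled peak. All 21964 pooled peaks that overlapped peaks of both replicates by 50% of either were in the replicated list, and so were 1490 others that did not. The 7085 pooled peaks left out had a median width of 230 bp and a median fold of 2.51, and 27.7% of them lay at an annotated start, against 70.5% of replicated peaks. Peaks on other contigs (13 to 20 per list) were left out. No peak reached beyond the end of its chromosome in the GRCm38.p6 assembly, which has the coordinates of mm10.

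Genes came from the GENCODE M21 annotation of that assembly, with 21938 protein-coding genes on chromosomes 1 to 19, X and Y. A gene was marked if a replicated peak overlapped the window of 1000 bp to either side of any of its transcript starts by at least 1 bp. Domains were replicated peaks joined across gaps of at most 1000 bp, and a gene's domain was the widest that overlapped its windows. Broad domains were the widest 5%. Distal peaks had no start of any annotated gene within 1000 bp. Promoter CpG content was the observed over expected CpG ratio in 2001 bp around the gene's 5' end, in deciles over protein-coding genes. Coordinates are given from 1.

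Before the data were examined, 20 gene lists with 419 genes and 3 gene families defined by symbol were fixed, and all symbols matched the annotation. Rpl13a and Rplp0 stand in both the housekeeping and the ribosomal list. The rule for the genes named in the text was also fixed then: the 15 widest domains with 1 gene each, from each list the 2 marked members with the widest domains and the first 2 unmarked members by alphabet, the 5 promoter peaks of highest fold, the 5 widest domains with no start within 5000 bp, and the 3 genes per replicate with the widest peak among those marked in that replicate alone. A few further members of short lists were named after their values were seen.

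Lists were compared by Fisher's exact test, two-sided, at a threshold of 0.05 after Benjamini-Hochberg adjustment. For marking, the background was all other protein-coding genes, with adjustment over the 23 lists. For broad domains, marked members were compared with the other marked protein-coding genes, with adjustment over the 19 lists with at least 5 marked members. Genes are not replicates, so these tests describe the lists in these libraries. Median widths were placed as percentiles among 10000 seeded random lists of the same size drawn from marked genes, with limits at 2.5 and 97.5 and no p-value. Chance overlap of the replicates came from 100 random placements of the peaks on their own chromosomes. Values per replicate are means ± SD of the 2 replicates' own lists. Widths in the replicates' own lists were joined in the same way.

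The alternatives tried were stricter q-value filters, the upper part of each list by fold, other promoter widths, only the gene's 5' end, a larger required overlap, the pooled list, each replicate's own list, other gaps for joining, other limits for broad and distal, random lists matched on CpG content, and fold in place of width. Further alternatives were added after the data were seen: the background without receptor genes, matching on the number of CpG in a wider window of 10001 bp around the gene's 5' end or on the number of starts, only domains of 1 protein-coding gene, and only peaks at the start of 1 protein-coding gene.

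The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Overlaps and joined domains were checked against bedtools 2.31.1, with the same counts of 24059 overlapping peaks and 20383 domains. The list tests were tested on simulated data over 21938 genes. With 200 genes in lists of 20 simulated as marked more often than the rest, 93.5% of the lists were called higher in list marking. With 200 marked less often, 98% were called lower, and 0.625% of unchanged lists were called. The simulated shifts were large: nearly all raised genes and a small minority of lowered genes were marked, against 65.9% of the rest. These rates do not hold for smaller differences or shorter lists. In the breadth comparison, run on 14462 genes, multiplying the widths of 200 genes by 1.25 placed 40% of the lists at or above the 97.5th percentile, by 1.5 placed 92% there and by 2 placed 100% there.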

Results

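Trimethylation of lysine 4 on histone H3 (H3K4me3), a chromatin mark found mainly around the transcription starts of genes, was mapped by chromatin immunoprecipitation and sequencing in mouse forebrain at embryonic day 12.5. Forebrain was taken from embryos of strain B6NCrl, with males and females pooled. The series held 1 group with 2 biological replicates, each a separate pool of tissue: replicate 1 came from 120 embryos and replicate 2 from 68. The deposited lists held peaks but no read counts, so the sequencing depth of each library is unknown. On chromosomes 1 to 19, X and Y, replicate 1 had 29092 peaks and replicate 2 had 28033 (28562.5 ± 749, SD, n = 2). The peaks of replicate 1 covered 36.1 Mb and those of replicate 2 covered 35.7 Mb (35.9 ± 0.222 Mb, SD, n = 2), about 1.32% and 1.31% of these chromosomes. The authors' list of replicated peaks held 23454 peaks with a median width of 1419.5 bp over 38.3 Mb, and it is the list behind the gene results that follow. With 1 group, the design held no comparison between conditions, and the only contrast among samples was between the replicates.

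The 2 pools of forebrain carried H3K4me3 at largely shared positions. Of the peaks of replicate 1, 24059 (82.7%) overlapped a peak of replicate 2 by at least 1 bp, and 23919 peaks of replicate 2 (85.3%) overlapped replicate 1. When the same peaks were placed at random on their chromosomes, the overlap averaged 2.63% and 2.69%, and the highest of 100 placements reached 2.89% and 2.92%. The covered bases shared by both replicates came to 32.5 Mb, a Jaccard index of 0.828. Peaks that did not overlap were short, with a median of 217 bp for 5033 peaks of replicate 1 and 225 bp for 4114 peaks of replicate 2. When the peaks of replicate 1 were put into 4 groups of about equal size by their deposited fold enrichment, 42.3% of the lowest group overlapped replicate 2, against 88.8%, 99.99% and 100% in groups 2, 3 and 4. The groups of replicate 2 gave 49.0%, 92.9%, 100% and 100%. Among 19338 peak pairs that overlapped one to one, the widths correlated across peaks of the 2 lists with a Spearman rho of 0.977, where peaks are not independent replicates, and 91.5% of the pairs had widths within 1.5 times of each other. The summits of a pair lay a median of 38 bp apart.

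**Figure D1:**
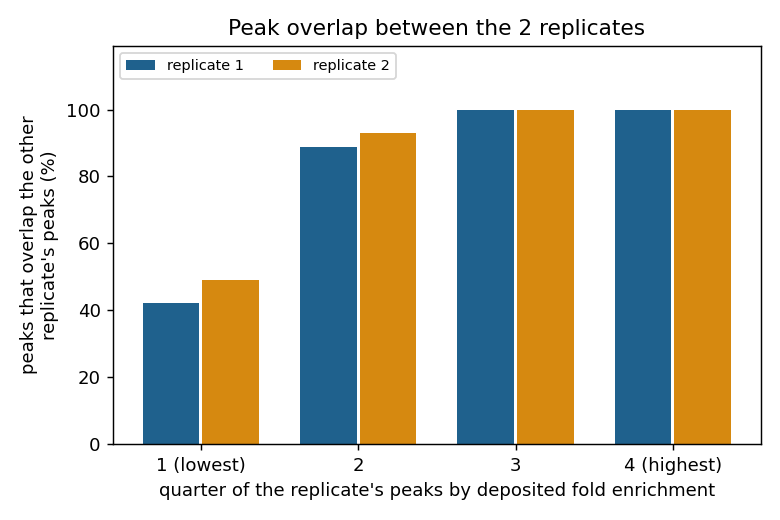
Percent of each replicate's peaks that overlap a peak of the other replicate by at least 1 bp (vertical axis), by group of deposited fold enrichment within that replicate's list (horizontal axis, 4 groups of about equal size), with 1 bar per replicate. The bars stand at 42.3% and 49.0% in the lowest group and at 100% for both replicates in the highest.

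Most protein-coding genes carried the mark, and the fixed lists of forebrain regulators, neural progenitor genes and newborn neuron genes did so completely. Of 21938 protein-coding genes, 14462 (65.9%) had a replicated peak within 1000 bp of an annotated transcript start. The replicates' own lists marked 14530 and 14505 genes (14517.5 ± 17.7, SD, n = 2), of which 14405 were marked in both. All 21 pallial regulators (transcription factors of the cortex and its surroundings, such as Pax6 and Nr2f2), all 22 subpallial regulators and marker genes (such as Dlx1 and Dlx2 of the ganglionic eminences) and all 20 diencephalic regulators (such as Lhx5 and Lhx9) were marked, and each list was marked completely in both replicates. The same held for 22 neural progenitor genes, 22 newborn neuron genes, 30 genes of patterning signals (such as Ptch1, the hedgehog receptor, and Axin2, a feedback gene of Wnt signalling) and 26 housekeeping genes. Each of these 7 lists was marked more often than all other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 23 lists). The highest adjusted p of the 7 was 0.000881, for the diencephalic list.

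Genes of more caudal brain regions and of mature neurons were also marked in forebrain. Of 20 midbrain and hindbrain regulators 19 were marked, among them Gata3 and Mafb, and Phox2b, a regulator of autonomic and hindbrain neurons, was not. With promoter windows of 2500 bp to either side the share of this list was 100%, so the exception depends on the window. Of 20 mature neuron genes 19 were marked, including Slc32a1 and Slc17a6, which encode vesicular transporters of inhibitory transmitters and of glutamate, and the neuropeptide gene Vip was not. Both lists were marked more often than other genes (adjusted p = 0.0063 in Fisher's exact test for each). Ribosomal protein genes were marked at 79 of 82 (adjusted p = 2.37e-10, Fisher's exact test), and the exceptions were the paralogs Rpl10l, Rpl39l and Rpl3l. Against 10000 random lists matched on the CpG content of the promoter, the subpallial, diencephalic, midbrain and hindbrain, and ribosomal lists lay within the middle 95% of random shares or at their upper limit, at percentiles of 85.0, 96.7, 45.0 and 85.8, because matched genes were marked at a mean of 95.6%, 93.1%, 95.3% and 94.3%. With only the upper part of the replicated list by fold, 4 lists were marked more often (progenitor, newborn neuron, housekeeping and ribosomal genes). The pallial (adjusted p = 0.0642), subpallial (0.311), diencephalic (0.0549), patterning (0.246) and mature neuron (0.524) lists then gave no call in Fisher's exact test, and midbrain and hindbrain regulators were marked less often (10%, adjusted p = 9.82e-05, Fisher's exact test).

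Genes of microglia, of other organs, of early embryos and germ cells, of red blood cells and of sensory receptors were marked less often. Among 16 microglia and macrophage genes only Tmem119 had a replicated peak (adjusted p = 4.82e-06, Fisher's exact test), with 863 bp and a fold enrichment of 4.41. Aif1 and C1qa had none. The width at Tmem119 was 365 bp in replicate 1 and 648 bp in replicate 2. The count moved with the list: 2 of 16 genes (12.5%) were marked by the peaks of replicate 1 alone, 3 (18.75%) by those of replicate 2 alone and 4 (25%) by the pooled list, and the share stayed below that of other genes in each (highest adjusted p = 0.00153, Fisher's exact test). Of 28 effector genes of other lineages, such as Acta1 of skeletal muscle and Afp of fetal liver, only Sftpc and Ckm were marked (adjusted p = 6.68e-10, Fisher's exact test). Both domains held the start of a neighbour, Bmp1 beside Sftpc and Klc3 beside Ckm, and the one assigned to Ckm ended before that gene. With only peaks at the start of 1 protein-coding gene, an alternative chosen after the data were seen, no effector gene was marked (0%, adjusted p = 3.85e-09, Fisher's exact test). Pluripotency and germline genes were marked at 6 of 18, with Klf4 and Esrrb marked and Dppa3 and Dppa5a not (adjusted p = 0.00821, Fisher's exact test). Of 1135 olfactory receptor genes 3 were marked, and of 331 vomeronasal receptor genes 1 was, Vmn1r4, whose domain also held the start of Nt5c3. With only peaks at the start of 1 protein-coding gene the vomeronasal share was 0%. Both shares were lower than among other genes by the same test. Random lists matched on promoter CpG content were marked at a mean of only 8.54% for olfactory and 7.99% for vomeronasal receptor genes. The matched means were 30.6% for effector genes, 27.7% for microglia and macrophage genes and 66.6% for pluripotency and germline genes. Each of these lists still lay below its matched lists, at percentiles of 0, 0, 0.05, 1.37 and 0 in that order. For all but the last, the gap to matched genes was smaller than that to other genes. Of 16 erythroid genes 6 were marked, with Klf1 and Epor among them and Alas2 and Gata1 not (adjusted p = 0.0439, Fisher's exact test). The erythroid call did not hold with the pooled peak list (adjusted p = 0.0816, Fisher's exact test) or against CpG-matched lists (percentile 80.4). Nor did it hold with only peaks at the start of 1 protein-coding gene (adjusted p = 0.266, Fisher's exact test). The erythroid share there stayed at 37.5%, while that of other genes fell to 53.4%. The pluripotency and germline call was also lost with only peaks at the start of 1 protein-coding gene (adjusted p = 0.147, Fisher's exact test).

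The other 7 lists were marked at shares that did not differ from all other genes by Fisher's exact test. Astrocyte genes were marked at 10 of 13, without Aqp4, Gfap and S100b, and oligodendrocyte genes at 8 of 14, with Pdgfra and Nkx6-2 but not Gpr17 or Mag. Endothelial and mural genes were marked at 13 of 20, mesenchyme and meninges genes at 12 of 16 and choroid plexus genes at 6 of 10, where the effectors Aqp1, Folr1, Kcne2 and Ttr were the unmarked members. The Hox genes, which specify position along the trunk and hindbrain, were marked at 26 of 39 (66.7%), and regulators of other lineages, such as Gata6 and Gsc, at 18 of 26 (69.2%). In the replicated list, the Hox genes and the regulators of other lineages fell below random lists matched on promoter CpG content (percentiles of 0 and 0.545). Matched genes were marked at a mean of 90.0% and 84.2%. The pooled list marked more of both, 82.1% of Hox genes and 84.6% of regulators of other lineages. Matched lists were not drawn for the pooled list, so the shortfall is shown only for the replicated list. With only the upper part of the replicated list by fold, 5 of these 7 lists were marked less often (Fisher's exact test): Hox genes (5.13%, adjusted p = 2.67e-10), regulators of other lineages (7.69%, 2.47e-06), endothelial and mural genes (15%, 0.000791), oligodendrocyte genes (21.4%, 0.023) and mesenchyme and meninges genes (25%, 0.032). S100b, Rpl3l, Kcne2 and Ttr were named after their values were seen, to complete the short rows of unmarked members.

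**Figure D2:**
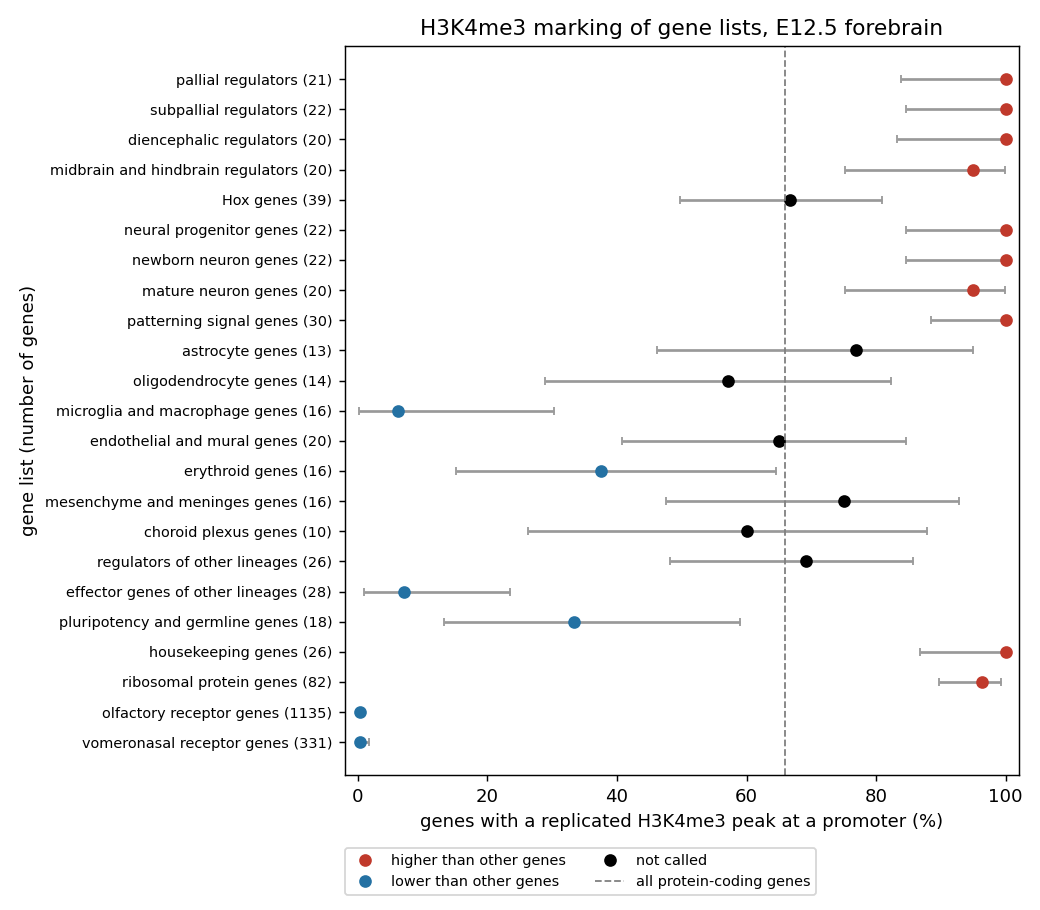
Percent of each list's genes with a replicated H3K4me3 peak within 1000 bp of a transcript start (horizontal axis), 1 row per list with its number of genes. Whiskers are exact 95% binomial intervals over genes, colours give the call of Fisher's exact test against all other protein-coding genes, and the dashed line marks 65.9%. The 7 lists at 100% include the pallial, subpallial and diencephalic regulators, and the microglia and macrophage list stands at 6.25%.

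Pou3f3, Nr2f2, Dlx1 with Dlx2, Pax6 and Lhx2 lay in the 5 widest H3K4me3 domains. Replicated peaks were joined across gaps of at most 1000 bp into 20383 domains with a median width of 1660 bp, and the marked protein-coding genes had a median of 2199 bp. The widest single replicated peak had 21076 bp, so the order of the widest domains depends on joining, and that of Nr2f2 joined 9 peaks. Without joining, the widths of 38 named genes moved by more than the SD of the replicates and those of 24 did not. The widest domain, 31173 bp on chromosome 1 from 42683553 to 42714725 (mm10), contained the whole of Pou3f3 (42695768 to 42703176), a transcription factor of neural progenitors and upper layer neurons. Its width was 31121 ± 79.2 bp in the replicates' own lists (SD, n = 2). The domain of Nr2f2 on chromosome 7, from 70342873 to 70371714, measured 28842 bp (28537 ± 256 bp, SD, n = 2) and contained the whole gene. A domain of 23879 bp on chromosome 2, from 71523370 to 71547248, contained both Dlx1 and Dlx2, neighbours that direct inhibitory neuron development (23041 ± 634 bp, SD, n = 2). Pax6, a regulator of cortical progenitors, had 23855 bp on chromosome 2 from 105666712 to 105690566 (23296.5 ± 764 bp, SD, n = 2), which took in the 5' part of the gene. Lhx2 followed with 23771 bp, Meis2 with 22830 bp, and a domain of 22637 bp on chromosome 12, from 49373671 to 49396307, contained Foxg1, a regulator of the telencephalon, and the overlapping gene model Gm43517. The other members of the 15 widest were Sox2 (19019 bp), Sox1, Emx2 (17939 bp), Nr2f1 (17516 bp), Mn1 (17471 bp), Dlx6 (17385 bp), Lhx5 (16773 bp) and Nfib (16753 bp). The domain of Sox1 measured 18811 bp in the replicated list but 8832.5 ± 14.8 bp in the replicates' own lists (SD, n = 2).

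The same lists stood apart as groups. The median width was 9104 bp for marked pallial regulators (8996 ± 73.5 bp in the replicates' own lists, SD, n = 2), 9281.0 bp for subpallial regulators (9671.5 ± 695 bp), 6168 bp for neural progenitor genes (6019 ± 57.3 bp), 5086.5 bp for diencephalic regulators (5281 ± 133 bp) and 4862.5 bp for patterning signal genes (4629.5 ± 81.3 bp). All 5 lay at percentile 100 among the medians of 10000 random lists of the same size from marked genes, as did newborn neuron genes at 3813 bp, with Myt1l (12727 bp) and Tubb3 (7796 bp) widest in the replicated list. In the replicates' own lists the domain of Myt1l measured only 6046.5 ± 306 bp (SD, n = 2), less than that of Tubb3 at 6918.5 ± 1039 bp, so their order depends on the list. These percentiles describe the libraries and carry no p-value. Choroid plexus genes reached 5248.5 bp over 6 marked genes, led by Otx2 (14437 bp) and Msx1 (7016 bp). Housekeeping genes had 3124.5 bp, midbrain and hindbrain regulators 3066 bp, and ribosomal protein genes 2732 bp, all above the middle 95% of random medians. Mature neuron genes (2828 bp) and mesenchyme and meninges genes (3144 bp) also passed that limit, at percentiles of 97.54 and 98.9, but neither did so in the list of replicate 1 alone (64.0 and 97.3) or of replicate 2 alone (54.1 and 57.3). The percentile of the midbrain and hindbrain list fell from 99.4 to 22.6 when random lists were matched on the number of CpG in a wider window around the gene's 5' end, an alternative chosen after the data were seen. The same matching took mesenchyme and meninges genes to 72.4, and matching on CpG decile took them to 96.7, within the middle 95%. Without joining of peaks, 7 lists in place of 12 lay above the middle 95%. The 5 that came within it were housekeeping genes (percentile 86.3), midbrain and hindbrain regulators (81.3), choroid plexus genes (95.54), mature neuron genes (70.4) and mesenchyme and meninges genes (89.6). Over domains of 1 protein-coding gene housekeeping genes also came within it (96.4).

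Narrow domains were found at Hox genes and at 3 further lists. Marked Hox genes had a median of 801.5 bp (634.5 ± 223 bp in the replicates' own lists, SD, n = 2) at percentile 0, and the widest, at Hoxc6, was 2191 bp. Regulators of other lineages had 1404.5 bp (1266.25 ± 39.95 bp, percentile 0.02), oligodendrocyte genes 1196 bp over 8 genes (percentile 0.23) and pluripotency and germline genes 1243.5 bp over 6 genes (percentile 0.755). Endothelial and mural genes, with a median of 2087 bp, and astrocyte genes, with 1811.5 bp, lay within the range of random lists, although Fgfr3 in the astrocyte list had 8914 bp. Erythroid genes had 1432 bp at percentile 2.69, and percentiles of 1.55 and 1.565 from the lists of replicate 2 and replicate 1 alone. With gaps of up to 3000 bp joined, the oligodendrocyte list and the regulators of other lineages came within the range of random lists, at percentiles of 5.81 and 7.15. Over domains of 1 protein-coding gene the oligodendrocyte list also came within it (percentile 2.63).

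**Figure D3:**
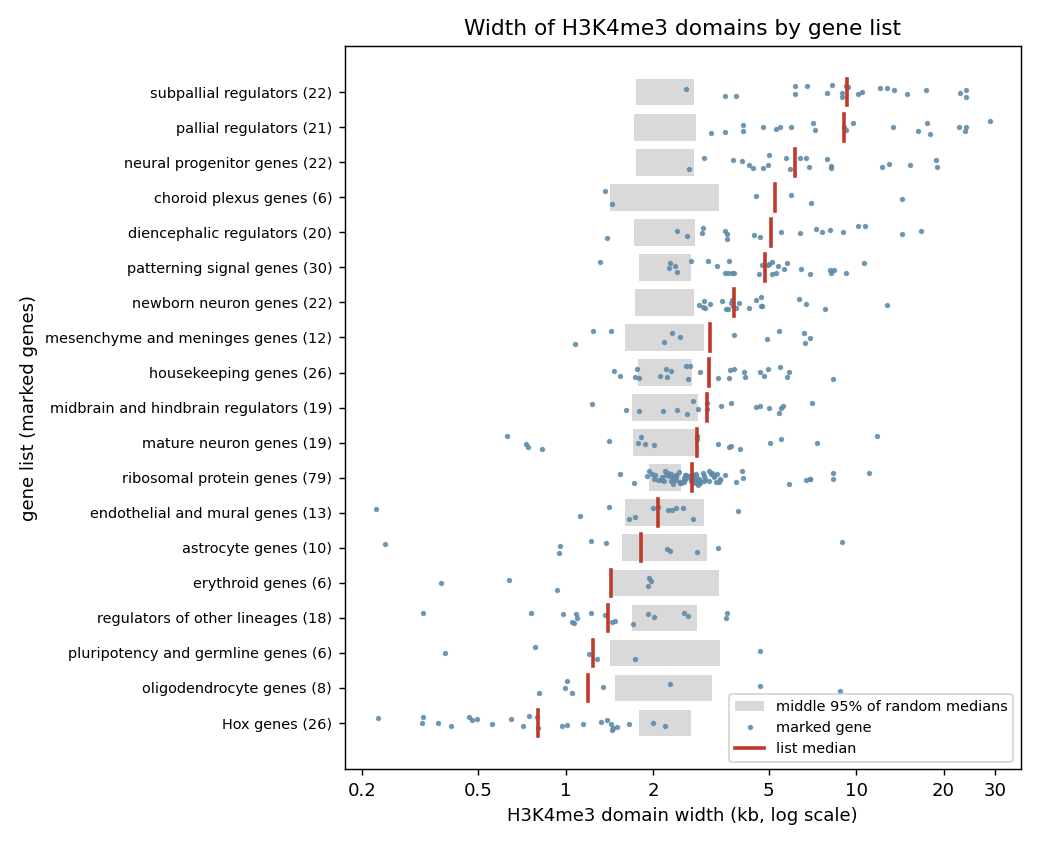
Width of the H3K4me3 domain of each marked gene (points, horizontal log axis in kb), 1 row per list with its number of marked genes and ordered by the list median (vertical lines). Grey bands hold the middle 95% of medians of 10000 random lists of the same size. Medians run from 801.5 bp for Hox genes to 9281.0 bp for subpallial regulators.

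The widest 5% of domains were 1020 domains of at least 4412.9 bp, and 95% of them lay within 1000 bp of a protein-coding start. Of the marked protein-coding genes, 1153 (7.97%) had such a domain. Among marked members, 19 of 22 subpallial regulators, 17 of 21 pallial regulators and 17 of 22 neural progenitor genes had such a domain (adjusted p = 2.73e-17, 7.95e-15 and 2.16e-14, Fisher's exact test). Neighbouring genes can share a domain, so the 19 subpallial genes had 18 distinct broad domains. The share was also higher than among other marked genes for patterning signal genes (17 of 30), diencephalic regulators (12 of 20), choroid plexus genes (4 of 6), newborn neuron genes (8 of 22), midbrain and hindbrain regulators (7 of 19), mesenchyme and meninges genes (5 of 12, with Prrx1 and Foxc1 widest) and housekeeping genes (7 of 26), with adjusted p between 3.98e-11 and 0.00652 in Fisher's exact test. No Hox gene of 26, no regulator of other lineages of 18 and no endothelial or mural gene of 13 had one, which did not pass the test at the limit of 5% (adjusted p = 0.385, 0.498 and 0.69, Fisher's exact test). The midbrain and hindbrain call did not hold in the list of replicate 1 alone, which gave 21.1% broad (adjusted p = 0.143, Fisher's exact test). Without joining of peaks the midbrain and hindbrain, mesenchyme, choroid plexus and housekeeping calls were lost, and with only domains of 1 protein-coding gene the housekeeping call was too (adjusted p = 0.0783, Fisher's exact test). Among the widest 1% of domains the calls of newborn neuron genes (9.09%, adjusted p = 0.137), choroid plexus genes (0.226), housekeeping genes (0.557), midbrain and hindbrain regulators (1) and mesenchyme and meninges genes (1) were lost (Fisher's exact test).

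Width and fold enrichment ordered the gene lists differently. The deposited fold enrichment is the authors' value per peak and ranks genes here only within the replicated list, with the highest peak at each gene's promoters. Housekeeping and ribosomal protein genes had the highest medians, 57.0 and 56.2, at percentiles of 99.9 and 100 among random marked lists, whose medians centred on 45.1. Neural progenitor genes had 48.5 (percentile 76.7). Pallial regulators had 37.6 (percentile 8.31) and subpallial regulators 29.3 (percentile 0.3). Diencephalic regulators had 18.5, midbrain and hindbrain regulators 15.5 and Hox genes 5.73, each at percentile 0. The domain of Lhx5 was 16773 bp wide with a highest fold of 18.8, whereas that of Pou3f3 had 68.4. The 5 promoter peaks with the highest fold lay at Arid1a (80.3), a subunit of a chromatin remodelling complex, Lrrc47 (77.0), Sfpq (76.6), Msi1 (75.6), which encodes an RNA-binding protein of neural progenitors, and Nacc1 (75.5). The Arid1a peak lay on chromosome 4 from 133749758 to 133757910.

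**Figure D4:**
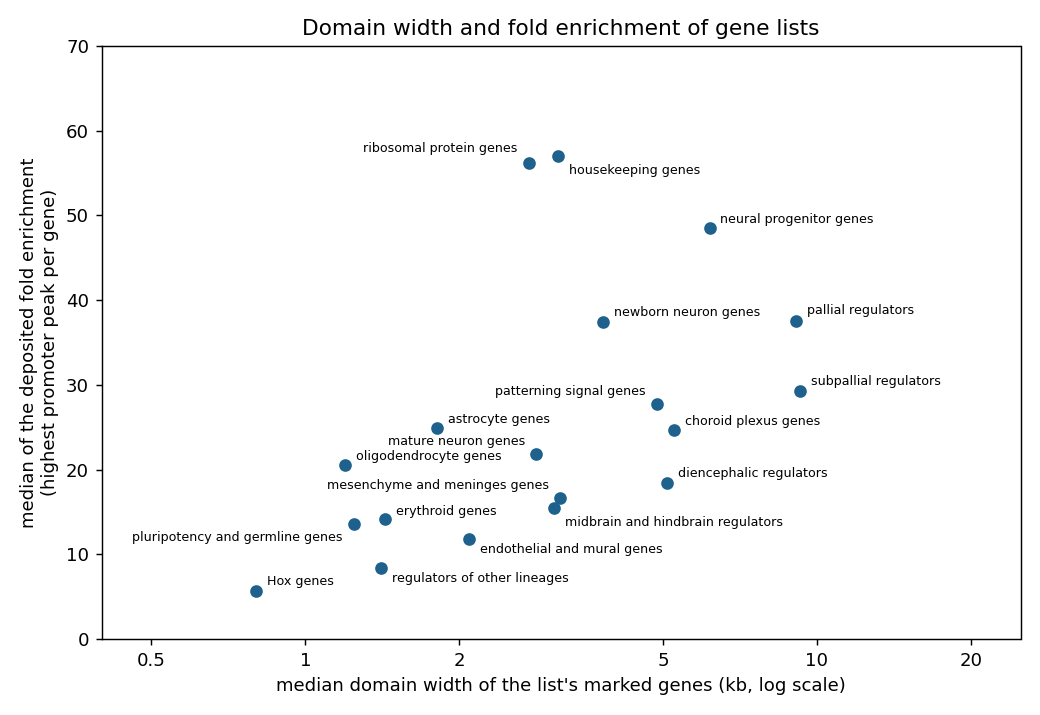
Median of the deposited fold enrichment at the promoters of each list's marked genes (vertical axis, no unit) against the median width of their domains (horizontal log axis in kb), with 1 point per list. Subpallial regulators lie at 9281.0 bp and a fold of 29.3, and housekeeping genes at 3124.5 bp and a fold of 57.0.

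Peaks away from annotated starts were numerous, short and low. Of the 23454 replicated peaks, 6914 (29.5%) had no annotated start of any gene type within 1000 bp. In the replicates' own lists the share was 36.2 ± 0.776% (SD, n = 2). Of these distal peaks 3045 (44.0%) were intergenic, 2576 (37.3%) intronic and 1293 (18.7%) exonic. Their median width was 599 bp and their median fold 4.54, against 1845 bp and 38.3 for peaks at a start. The widest domain with no start within 5000 bp, 7048 bp on chromosome 13 from 21166630 to 21173677, was intergenic and lay 5768 bp from the nearest protein-coding start, that of Trim27. A domain of 6700 bp on chromosome 2 from 115854401 to 115861100 lay beyond the 3' end of Meis2, annotated at 115863064. The next were 2 intergenic domains, of 6493 bp at 5848 bp from the nearest protein-coding start, that of Dhx37, and of 6161 bp at 12020 bp from that of Cbx8, and an intronic domain of 5975 bp at 41788 bp from its nearest protein-coding start, that of Ostm1. Among the peaks in the upper part of the list by fold (11727 peaks), 3.27% were distal.

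Few genes were marked in only 1 replicate. Replicate 1 alone marked 125 protein-coding genes and replicate 2 alone 100, which were 0.57% and 0.456% of all. Of the fixed lists' members, 23 were marked in 1 replicate only, 9 of them in replicate 1 and 14 in replicate 2. With 1 library for each pool size, no test between the pools could be made. The Hox list held 7 of the 23 and regulators of other lineages 4, while the pallial, subpallial, diencephalic, progenitor and both neuron lists held none. The genes with the widest peak in only replicate 1 were Tnnc1, Tchh and Sftpc, and in only replicate 2 Gm28035, Ptpn6 and Foxh1. All 6 were marked in the replicated list, and at all 6 the peak overlapped a peak of the other replicate that did not reach the window around the starts. This held for 5 of the 125 genes and for 9 of the 100, and the peaks of the rest overlapped none. The domains of 5 of the 6 also held the start of a neighbouring gene (Nisch, Bmp1, Lrrc8a, Grcc10 and Ppp1r16a), so their peaks are not shown to belong to the named gene. The domain of Tchh held no neighbour's start. It ran from 93443107 to 93448199, inside the gene (93442330 to 93449077) and without its 5' end, so it is not shown to mark the promoter.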

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

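The number of marked genes stayed between 11974 and 14683 under all 10 alternatives. Matching on the number of CpG in the wider window and the use of only domains of 1 protein-coding gene were chosen after the data were seen; the other alternatives below were fixed before. No alternative gives the depth of the libraries, which limits what the weakest peaks can show.

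Keeping the upper part of each list by fold left 14546 peaks of replicate 1, 14035 of replicate 2, 15275 pooled and 11727 replicated peaks, by construction. The overlap of replicate 1 with replicate 2 moved to 88.1% at a −log10 q of 2, 94.998% at 5, 95.5% in the upper part by fold and 79.8% when 50% of the shorter peak had to overlap. That of replicate 2 moved to 93.7% at 5, 98.7% and 82.4%. List members marked in 1 replicate only fell to 7 at a −log10 q of 5. The share of distal peaks was 26.5% at a −log10 q of 5, 3.27% in the upper part by fold, 35.7% to 36.8% without either replicate, 39.4% in the pooled list, and 22.1% and 16.2% with no start within 2500 or 5000 bp.

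In the upper part by fold, 4 lists were marked more often and 12 less often. Shares there turned below the rest for diencephalic regulators (30%), midbrain and hindbrain regulators (10%), Hox genes (5.13%), mature neuron genes (45%), mesenchyme and meninges genes (25%) and regulators of other lineages (7.69%); the low fold of their peaks accounts for this by construction. Against CpG-matched lists 6 were marked more often, and the side changed for midbrain and hindbrain regulators (percentile 44.98), Hox genes (0), erythroid genes (80.38) and regulators of other lineages (0.545).

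Without joining, 7 lists were above the middle 95% of random widths and 6 had more broad domains. With fold in place of width 2 lists were above it and 13 below. The side changed for pallial (8.31), subpallial (0.3), diencephalic (0) and midbrain and hindbrain regulators (0), newborn neuron (6.89), mature neuron (0.03), patterning signal (0.03), mesenchyme and meninges (0.03) and choroid plexus genes (2.6). Matching on the number of CpG in the wider window took midbrain and hindbrain regulators to percentile 22.6. For the widest 1% of domains 5 lists were called, with a share of 0 for midbrain and hindbrain regulators and for mesenchyme and meninges genes. With only domains of 1 protein-coding gene the broad share of ribosomal protein genes fell to 0%. Calls were also gained: 11 lists in place of 10 had more broad domains with gaps of up to 3000 bp joined, and 11 with the widest 10% of domains. Where no construction is named, the cause was not tested.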

Other observations

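The tests split by blood and vessel part and the CpG test of the midbrain and hindbrain list were chosen only after related results were seen. The chance that a gene carried H3K4me3 followed the CpG content of its promoter. In the lowest decile of CpG content 3.51% of protein-coding genes were marked, in the fourth 46.6%, in the fifth 84.7% and in the highest 99.7%. Peak summits lay on the gene side of the start: of replicated peaks with a summit within 1000 bp of a protein-coding start, 80.3% had it downstream, at a median of 132 bp, and the replicates' own lists gave medians of 131 bp and 130 bp. Chromosome X had 51.7% of its protein-coding genes marked, near chromosomes 7 (54.3%) and 14 (55.7%), and chromosome 12 had the highest share, at 80.9%. Without receptor genes the shares of X, 7 and 14 were 52.2%, 67.5% and 58.4%. On chromosome Y 4 of 183 genes were marked. The pools held both sexes, and whether reads can be placed on the Y genes was not tested, so this is not shown to be an absence of the mark.

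The marked share of noncoding genes fell once those near protein-coding starts were set aside, by an amount that differed among gene types. Of 5854 lincRNA genes 884 (15.1%) were marked, and 8.90% of those whose starts lay away from protein-coding starts. Antisense genes went from 35.5% to 7.19%, miRNA genes from 14.4% to 4.65% and processed transcripts from 54.3% to 27.1%. Processed pseudogenes changed little, from 1.87% to 1.31%. None of the 7 globin genes of the erythroid list had a replicated peak, although near-identical globin copies make this uncertain.

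Subpallial and diencephalic regulators and patterning signal genes stood above the middle 95% of random lists in width and below it in fold. Midbrain and hindbrain regulators, mature neuron genes and mesenchyme and meninges genes did so too, but without joining of peaks their widths came within it (percentiles of 81.3, 70.4 and 89.6), and the widths of the last 2 did so in each replicate's own list. For pallial, subpallial and diencephalic regulators, only CpG content by decile near the gene's 5' end is argued against as the source of the width. Their lowest width percentile was 100 in lists matched on CpG decile and 99.92 when matched on the number of CpG. The number of CpG was also matched by decile. The highest decile has no upper limit, so a CpG content above that of the matched genes stays open. Some domains reach beyond the wider window, as at Nr2f2, or lie away from the 5' end, as at Lmo3 and Tcf7l2. CpG content there was not matched and stays open. For midbrain and hindbrain regulators, at 98.8 and 22.645, CpG content near the 5' end stays open too. Joined protein-coding neighbours are argued against, since the lowest percentile over domains of 1 protein-coding gene was 99.84 for the 4 regulator lists. Starts of noncoding genes were not counted there, so joined noncoding neighbours stay open. In lists matched on width decile, subpallial, diencephalic, and midbrain and hindbrain regulators lay at a fold percentile of 0. Matched genes had median folds of 50.6, 50.2 and 49.6. For midbrain and hindbrain regulators, with a median width of 3066 bp, this argues against width as the source of the low fold. The widest decile has no upper limit, and 19 of 22 subpallial and 12 of 20 diencephalic regulators had broad domains, which lie in it. Their matched genes could be narrower, so width stays open for both lists. No biological explanation was tested.

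Blood and vessel genes were marked at 20 of 52 (38.5%), a share at percentile 26.62 of lists matched on promoter CpG content (middle 95% from 30.8% to 51.9%). CpG content may thus account for the joint share, but the lists differed. Microglia and macrophage genes alone lay at percentile 1.37, below the limit of 2.5, with matched genes marked at a mean of 27.7%. Endothelial and mural genes lay at 57.3 and erythroid genes at 80.4. Promoters shared with a protein-coding neighbour are argued against for most of the marked blood and vessel genes. Of these, 5% (1 of 20) had peaks that all covered the start of another protein-coding gene, with noncoding neighbours not counted. Among all other marked genes the share was 17.4%, which did not differ (p = 0.233, Fisher's exact test). Cells of these types in the tissue stay open: of the genes in the 4 lowest CpG deciles 22.5% (9 of 40) were marked, against 20.8% of other genes (p = 0.845, Fisher's exact test) and 24.95% of other genes without receptor genes (p = 0.855). The microglia, macrophage and erythroid part stood at 17.2% (5 of 29, p = 0.819, and 0.397 without receptor genes, Fisher's exact test). The endothelial and mural part stood at 36.4% (4 of 11, p = 0.256, and 0.483 without receptor genes, Fisher's exact test). Neither part was decided, and what difference could be detected with so few genes was not tested. No biological explanation was tested.

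Distal replicated peaks were poor in repeats, with a median repeat-masked share of 9.65% against 23.4% to 25.2% in 100 random placements. Peaks at starts had 9.57%. This argues against repeated sequence as the source of the typical distal peak. The placements were not limited to sequence where reads can be mapped, and a median does not describe a subset, so repeats stay open for some of the peaks. Missing starts remain open in part: 10.9% (751 peaks) had a RefSeq transcript start within 1000 bp, so most had none in either annotation. Random placements gave 4.44% to 5.73%, but unlike the distal peaks they could fall at GENCODE starts. Of the peaks at such starts 91.7% had a RefSeq start, so the random share is likely too high for a like comparison. Their median CpG observed over expected ratio of 0.431 lay above the random range of 0.154 to 0.161 and below the 0.588 of peaks at starts, so CpG-rich sequence may be a source for part of them. No biological explanation was tested.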
